A study of Mus musculus with 26 samples.

How the data were processed

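Gene expression was measured by sequencing of poly(A) RNA, as 150 bp paired-end reads, in 26 libraries from KP cells, B16 cells and mouse lung tumours. The deposited values are raw counts per gene symbol with 1 column per library, per the labels. Reads were trimmed with Trim Galore 0.6.6, aligned with HISAT2 2.1.0 to mm10 and counted with featureCounts 1.6.4, and DESeq2 is named without a version, per the submitters' processing notes. The strand setting and the annotation version behind the counts are not given in the sources used here. In each table the values were whole numbers with different totals per library, as raw counts have.

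The 4 count tables hold 23537 (KP cells), 23658 (tumours), 25277 (B16) and 25277 (C271) genes. Each was normalized and fitted on its own, since the tables share no library. Among the genes of the KP cells 26 symbols had been turned into dates and were kept under those names. Genes kept by filterByExpr (min.count 10, min.total.count 15) numbered 12074, 15041, 13186 and 13025. Totals per library ran from 18.9 to 22.8 (KP cells), 16.2 to 18.6 (tumours), 17.4 to 21.9 (B16) and 15.6 to 18.8 (C271), in units of 1e6 counts.

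Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 and no threshold on the fold change. All 10 B16 libraries were fitted together with 1 coefficient per group, and the other tables with their own groups, in 9 comparisons in all. CPM values use TMM-scaled totals, and means and SDs of CPM are over the libraries of a group. Values after ± on the log2 scale are standard errors from the fit. A gene with 0 counts in a group is given as a bound that sets the group to 3 counts in total. Of 38 gene lists fixed before the data were examined, those with at least 5 measured members were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, and also with the correlation estimated per list and with fry. Adjustment was over the lists of a comparison.

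Genes were named by a rule set before the data were examined. It takes Tdg, Trp53 and Mavs in every library. It takes the 8 largest changes in each direction among genes past the threshold with a mean CPM of at least 2 and no overlap between groups, leaving out predicted genes. It takes up to 4 members of each list, those past the threshold with the largest change or, where fewer than 2 passed, those with the highest counts. Named outside this rule, after their values were seen, were Ifit1, Ddx58, Cdkn1a, Isg15 and Cdh1 in KP cells, and Mxi1 and Xist in tumours. The same holds in B16 cells for Trp53inp1, Plk2, Ifi27, Isg15, B2m, Dnmt1, Rn45s, Samd9l and Usp18, and for the genes shared between systems, and for Isg15 and Ifit1 in tumours. The Y-linked genes Ddx3y and Eif2s3y in tumours were named outside the rule as well.

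Simulated data were drawn from the means and library sizes of these libraries, with the same spread of a gene in all groups. The procedure was tested on them with 200 genes, of mean count at least 50, changed by a log2 fold change of 1 or 2. It recovered 8% and 74% of them in the KP cell design (11945 genes), 31% and 92% in the tumour design (14851 genes), and 93% and 100% in the C271 design (12860 genes). In the design of DKO against Trp53 KO it recovered 43% and 92% (12984 genes). The calls in these designs numbered 87, 133, 208 and 144, of which 5, 10, 15 and 9 were false, and no changed gene had the wrong sign. These rates do not cover genes with fewer counts or groups of unequal spread. In KP cells the chi-square per degree of freedom between libraries was 1.78 to 41.3 for WT pairs and 165 to 281 for KO pairs.

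Replicate numbers in the labels could mark shared preparation, so residuals of libraries with the same number were correlated. The correlations were 0.0306, 0.128 and -0.146 in KP cells and 0.147 and 0.0237 in tumours, and 2 of the 6 KP cell libraries correlated best with the library of their own number. The numbers were therefore not used as pairs. Nothing in the labels says that replicates are separate cultures, clones or animals, so the p-values measure the spread between these samples.

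Alternatives set before the data were examined were DESeq2 size factors, no filter on low counts, a mean CPM of at least 2, the Wald test of DESeq2 1.42.0, the replicate number as a block, leaving out each library, a log2 fold change of at least 1, and fits of the compared B16 groups alone. A left-out library can leave a group with 1 library, which is then assumed to vary like the others. Gene positions are those of GENCODE M21 on mm10. Comparisons of DKO with WT and Tdg KO and of TKO with WT, and fits that give each comparison with DKO a library of its own, were added after the data were seen.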

Results

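Poly(A) RNA of mouse cells and tumours was sequenced in 26 libraries that fall into 11 groups. KP cells, a mouse lung adenocarcinoma line, were compared as wild type (WT, n = 3) and Tdg knockout (KO, n = 3). KP cells were also treated with the compound C271 at 2.5 µM for 6 days (n = 2) or with its solvent DMSO (n = 2). Lung tumours driven by mutant Kras with Trp53 knocked out were taken with Tdg intact (KP tumours, n = 2) or with Tdg also knocked out (KPT tumours, n = 4). B16 cells, a mouse melanoma line, were WT, Tdg KO, Trp53 KO, knockout of Tdg and Trp53 together (DKO), or knockout of Tdg, Trp53 and Mavs (TKO), with n = 2 in each group. Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that also removes oxidised forms of methylcytosine. Trp53 encodes p53, and Mavs encodes the adaptor that passes signals from the double-stranded RNA sensors RIG-I and MDA5. The comparisons ask what loss of Tdg does to gene expression in cancer cells that lack p53, and what Mavs contributes.

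Each of the 4 count tables was fitted on its own. Totals ran from 15579476 to 22773778 counts per library. Nothing in the labels says whether replicates of the cell lines were separate cultures or clones, so the p-values measure the spread between these libraries, part of which may be technical. Some edited libraries had shifted chromosomes. The median log2 level of chromosome 6 against WT was -0.786 in KP Tdg KO replicate 2 and 0.0631 in replicate 3. That of chromosome 12 was -0.144 and -0.587 in B16 Tdg KO. Differences between clones could add to any comparison of knockout with WT, which was not tested. KP WT replicates 2 and 3 differed little beyond sampling noise, with a chi-square of 1.78 per degree of freedom, against 41.3 between WT replicates 1 and 2. The B16 WT pair gave 2.25, the C271 pair 3.40 and the DMSO pair 4.37, while pairs of knockout libraries gave 23.4 to 281. No pair was within sampling noise, and all libraries were kept as separate replicates. These values cannot tell separate samples from repeat preparations of the same sample.

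Tdg, which lies on chromosome 10 (82629828 to 82650799 in mm10, GENCODE M21), was measured first as a check of the labels, in counts per 1e6 counts (CPM). In KP cells Tdg was at 13.8, 19.9 and 20.3 CPM in the WT libraries and at 0.843, 1.78 and 2.70 CPM in the KO libraries. KP tumours had 27.7 and 26.1 CPM, and KPT tumours had 12.2, 13.4, 11.5 and 10.7 CPM, which is a log2 fold change of -1.17 ± 0.18 (SE, edgeR adjusted p = 0.0297). In B16 cells Tdg stood at 144 and 154 CPM in WT and at 177 and 150 CPM in Trp53 KO. Tdg was at 8.70 and 37.0 CPM in Tdg KO, at 14.9 and 16.5 CPM in DKO, and at 35.4 and 17.4 CPM in TKO. The C271 libraries had 16.2 and 17.3 CPM of Tdg against 17.0 and 15.4 CPM with DMSO. Trp53 (chromosome 11, 69580359 to 69591873) was at 200 and 196 CPM in B16 WT and at 204 and 181 CPM in B16 Tdg KO. It was at 58.6 and 18.0 CPM in Trp53 KO, at 61.1 and 76.0 CPM in DKO and at 17.5 and 43.2 CPM in TKO. In tumours, which hold cells with Trp53 intact as well, it was at 19.9 and 21.3 CPM in KP and at 27.2, 35.3, 28.4 and 27.1 CPM in KPT (edgeR adjusted p = 0.203). Mavs (chromosome 2, 131234063 to 131248025) was at 38.6 and 37.0 CPM in TKO and at 47.0 and 40.4 CPM in DKO, so its transcript level does not check the Mavs label. The edited position is not stated in the labels, and residual transcripts of a knocked-out gene can still be counted at the gene level.

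**Figure D1:**
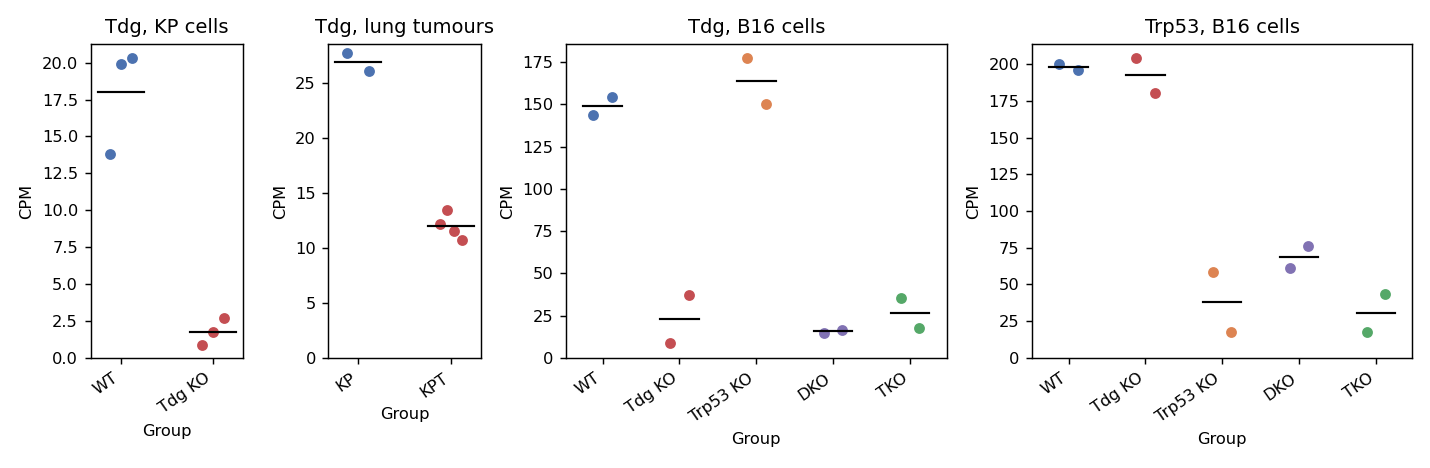
CPM of Tdg and Trp53 in each library, with points for libraries and a black bar for the group mean. Every library labelled Tdg KO, DKO or TKO lies below every library of its system with Tdg intact; the 2 KP tumours are at 27.7 and 26.1 CPM and the highest KPT tumour at 13.4 CPM.

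KP cells without Tdg expressed the neutrophil-attracting chemokines Cxcl5 and Cxcl1 at higher levels than WT cells and the keratin genes Krt20, Krt23 and Krt18 at lower levels. Cxcl5, a CXCR2 ligand that recruits neutrophils (chromosome 5, 90759360 to 90761624), rose from 13.1 ± 2.67 CPM to 651 ± 342 CPM (SD, n = 3 each), a log2 fold change of 5.63 ± 0.45. Its neighbour Cxcl1, with the same receptor, rose from 7.88 ± 1.15 to 331 ± 286 CPM. Complement component C3 rose from 0.245 ± 0.157 to 391 ± 371 CPM, and Slpi, a secreted protease inhibitor, rose from 0.814 ± 0.272 to 68.7 ± 52.6 CPM. On the other side, the simple-epithelium keratin Krt20 fell from 13.1 ± 2.20 to 0.134 ± 0.0402 CPM, and Krt23 from 13.9 ± 0.756 to 0.0600 ± 0.104 CPM.

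Of 12074 genes tested in KP cells, 71 changed (edgeR, adjusted p under 0.05), 34 upward and 37 downward, and 1491 had an unadjusted p under 0.05. All 71 had no overlap between the groups, which chance gives to 10% of unchanged genes with 3 against 3. Steap4, a metalloreductase, rose by 6.65 ± 1.05 on the log2 scale and the matrix proteoglycan Dcn by 5.45 ± 0.63. Nos2, the inducible nitric oxide synthase, was at 1 count in all WT libraries together and at 8.74 ± 7.49 CPM in the KO. Among genes that fell were Pcsk9, a regulator of the LDL receptor (log2 fold change -5.20 ± 0.40), the norrin gene Ndp (-4.61 ± 0.42), Lratd1 (-4.55 ± 0.71), Epb41l3 (-5.69 ± 0.79) and Tns4 (-6.30 ± 0.80). The desmosomal cadherin Dsc2 fell from 4.47 ± 0.730 CPM to 1 count in all KO libraries together.

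Of 28 measured NF-kB response genes, 3 rose over all genes tested (Cxcl1, Nfkbiz at 4.27 ± 0.54 and the RNase gene Zc3h12a at 2.94 ± 0.34), none fell, and 21 rose when adjusted over the list alone. The list ranked above other genes by camera (adjusted p = 3.84e-20, but adjusted p = 0.123 with an estimated correlation). Among 5 measured interferons and interferon-induced chemokines, Ccl5 (log2 fold change 4.23 ± 0.66) and Cxcl10 (3.22 ± 0.39) rose, and 3 rose when adjusted over the list alone (camera adjusted p = 1.10e-06, and adjusted p = 0.0847 with an estimated correlation). None of the 36 interferon-stimulated genes passed over all genes, while 11 rose when adjusted over the list alone (camera adjusted p = 4.18e-07, and adjusted p = 0.0847 with an estimated correlation). Ifit1 was at 4.27, 1.82 and 4.50 CPM in the KO libraries against 0.735, 0.900 and 0.446 CPM in WT, and Ddx58, the RIG-I gene, was at 11.3 ± 1.59 CPM in WT and 34.3 ± 13.5 CPM in the KO (SD, n = 3 each; edgeR adjusted p = 0.102). Of 10 epithelial genes 1 fell, Krt18 (-2.10 ± 0.21), and 5 fell when adjusted over the list alone (camera adjusted p = 2.39e-07, and adjusted p = 0.404 with an estimated correlation). Krt8, the keratin partner of Krt18, was at 957, 1284 and 1238 CPM in WT and at 72.6, 3.93 and 90.6 CPM in the KO. The KO libraries were apart in E-cadherin, Cdh1, at 5.45, 0.336 and 127 CPM against 38.0, 39.4 and 37.6 CPM in WT. Among 24 cholesterol biosynthesis genes only Pcsk9 passed (camera adjusted p = 3.91e-07, and adjusted p = 0.488 with an estimated correlation). Fibroblast markers moved both ways, with Dcn and Pdgfra (2.76 ± 0.38) higher and Cthrc1 (-2.48 ± 0.34) lower among 9 measured. Among 38 p53 target genes the death receptor gene Fas rose (4.94 ± 0.63).

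KO replicate 1 stood apart in single genes, with Cdkn1a at 67.8 CPM against 3.50 and 3.64 CPM in the other KO libraries, and Isg15 at 8.15 CPM against 0.720 and 0.495 CPM. The number of changed genes was 143, 139 and 290 without KO replicate 1, 2 or 3, and 0 by edgeR without WT replicate 1, 2 or 3 (827, 800 and 803 at an unadjusted p under 0.05). DESeq2's Wald test called 602 genes, which included all 71, with 373 upward and 229 downward.

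**Figure D2:**
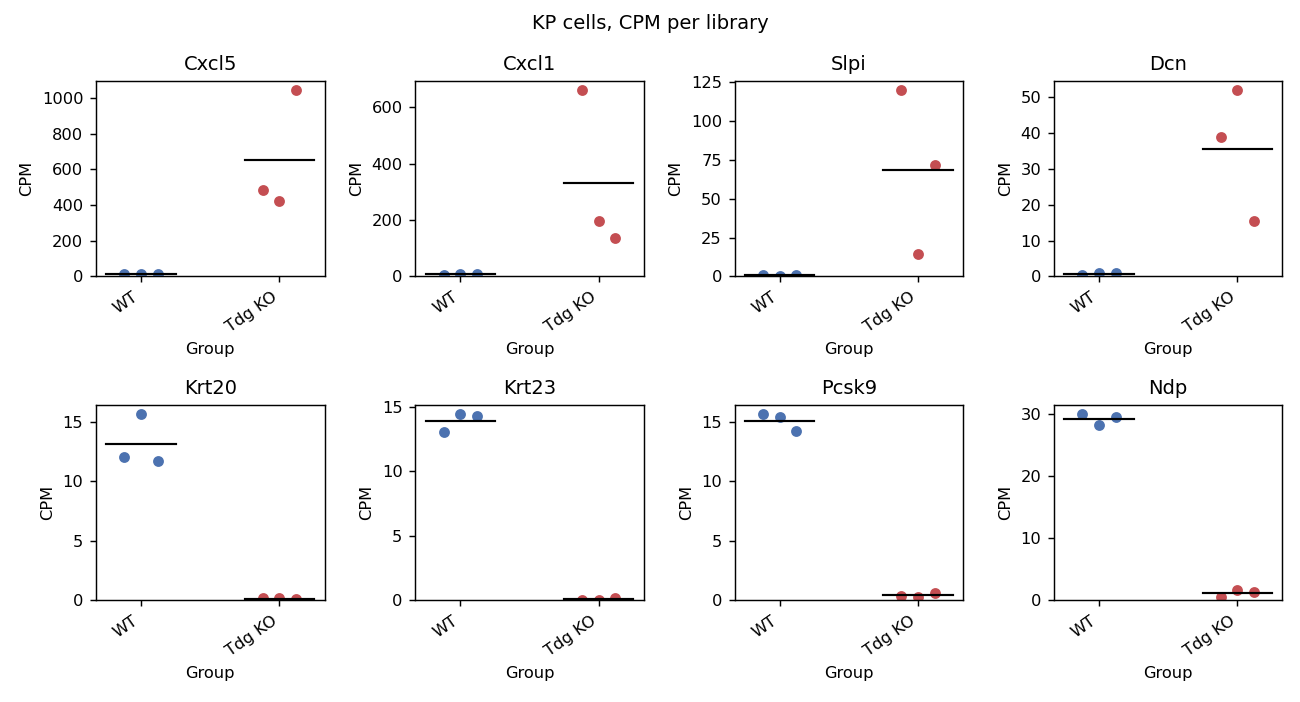
CPM of 8 named genes in each KP library (y axis, linear from 0; n = 3 per group), with points for libraries and a black bar for the group mean. Cxcl5 was between 426 and 1044 CPM in the KO libraries and at most 16.2 CPM in WT.

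KPT tumours had a lower median level of hypoxia and glycolysis genes than KP tumours and higher medians of fibroblast, endothelial, T cell and alveolar type 2 markers, though few single genes of these lists passed. The camera calls of these lists are lost with an estimated correlation (adjusted p = 0.370 to 0.591), and fry called 0 of the 36 lists tested in tumours. The neuronal and hypoxia-inducible enolase Eno2 fell from 27.2 ± 3.76 CPM (SD, n = 2) to 2.20 ± 0.492 CPM (SD, n = 4). Egln3, a HIF-induced prolyl hydroxylase, changed by -2.33 ± 0.32 on the log2 scale. Surfactant protein C, Sftpc, which marks alveolar type 2 cells, rose by 1.75 ± 0.28, from 11865 and 9716 CPM to between 26049 and 44481 CPM. The meiotic cohesin gene Rec8 rose from 1.86 ± 0.313 to 33.3 ± 10.8 CPM.

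Of 15041 genes tested, 152 changed (edgeR, adjusted p under 0.05), 54 upward and 98 downward, with 2565 at an unadjusted p under 0.05. Other genes that rose were Tmeff2 (log2 fold change 3.51 ± 0.58), complement component C7 (2.77 ± 0.48), the pantetheinase Vnn1 (2.72 ± 0.33), Pdlim3 (2.49 ± 0.38), the T cell receptor subunit Cd3e (2.37 ± 0.44), Dmtn (2.17 ± 0.35) and Msrb2 (2.17 ± 0.34). The transcription factor gene Pax9 (-6.07 ± 1.10), the foregut factor Pdx1 (-4.38 ± 0.78) and its neighbouring non-coding RNA Plut (-4.46 ± 0.69) fell. Serpina3h (-4.23 ± 0.41), the intestinal alkaline phosphatase Alpi (-3.89 ± 0.54), Grin1 (-3.17 ± 0.37) and Pianp (-4.35 ± 0.66) fell as well. The KP tumours differed between themselves for some of these, with Pax9 at 1.88 and 41.1 CPM.

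Of 29 hypoxia and glycolysis genes 5 fell (Egln3, Pfkp at -1.44 ± 0.18, Bnip3 at -1.34 ± 0.20, the glucose transporter Slc2a1 at -1.19 ± 0.18, and Mxi1), none rose, and 17 fell when adjusted over the list alone. Camera ranked the list below other genes (adjusted p = 2.61e-16, but adjusted p = 0.370 with an estimated correlation). Among 16 endothelial markers Car4 (1.84 ± 0.22) and Calcrl (1.19 ± 0.19) rose, and 10 rose when adjusted over the list alone (camera adjusted p = 3.43e-08, and adjusted p = 0.562 with an estimated correlation). Among 16 fibroblast markers Inmt rose (1.64 ± 0.31), and 8 rose when adjusted over the list alone (camera adjusted p = 6.48e-08, and adjusted p = 0.562 with an estimated correlation). Cd3e was the only one of 20 T cell markers past the threshold, with 2 when adjusted over the list alone (camera adjusted p = 1.55e-05, and adjusted p = 0.591 with an estimated correlation). None of 16 dendritic cell markers passed, and 4 rose when adjusted over the list alone (camera adjusted p = 4.15e-05, and adjusted p = 0.562 with an estimated correlation). Sftpc was the only one of 18 alveolar type 2 markers that passed, with 2 when adjusted over the list alone (camera adjusted p = 9.996e-05, and adjusted p = 0.591 with an estimated correlation). None of 24 macrophage and monocyte markers passed, with a median log2 fold change of 0.23 (camera adjusted p = 0.199, and adjusted p = 0.825 with an estimated correlation). The interferon-stimulated genes had a median log2 fold change of 0.00 over 52 genes with none past the threshold and 1 higher when adjusted over the list alone (camera adjusted p = 0.232, and adjusted p = 0.986 with an estimated correlation). That median was -0.20 without KP tumour replicate 1 (camera adjusted p = 0.0467) and 0.52 without KP tumour replicate 2, where camera also calls the list. The KP tumours differ in these genes, with Isg15 at 5.65 and 30.4 CPM and Ifit1 at 3.89 and 22.4 CPM. Tnfsf10, which encodes the death ligand TRAIL, rose (1.65 ± 0.26), as did Sting1, the adaptor of cytosolic DNA sensing (1.01 ± 0.16).

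The count of changed genes fell to 65 and 27 without KP tumour replicate 1 or 2, and to 13 and 28 without KPT tumour replicate 2 or 4, while DESeq2's Wald test called 936. The balance of directions depended on the fit, with 537 upward and 399 downward by DESeq2 and 174 upward and 109 downward by edgeR with the replicate number as a block. KPT tumour replicate 2 was from a female animal by its Xist level (1944 CPM, against at most 2.83 CPM in the other tumours).

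**Figure D3:**
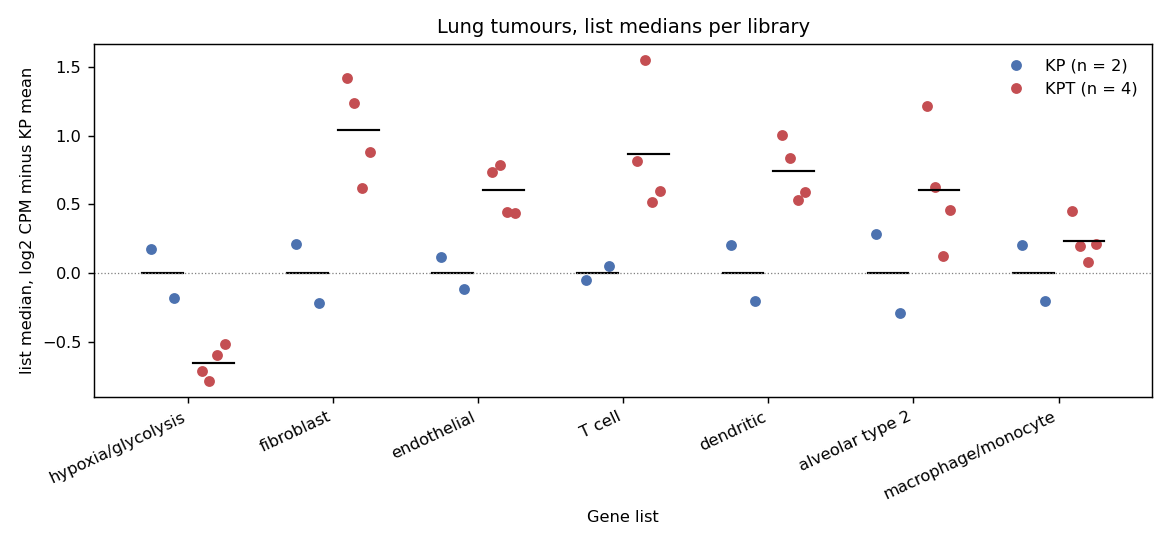
Median over each gene list of log2 CPM minus the mean of the KP tumours (y axis), per tumour library, with points for libraries and a black bar for the group mean. All 4 KPT tumours lie below both KP tumours for hypoxia and glycolysis genes and above both for fibroblast, endothelial, T cell and dendritic cell markers.

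KP cells treated with C271 for 6 days had higher levels of 27 of 33 NRF2 and xenobiotic response genes than the DMSO cells and lower levels of immediate-early genes such as Fos. The camera call of that list is lost with an estimated correlation (adjusted p = 0.174). Nqo1, a quinone reductase and standard NRF2 target, rose from 9.74 ± 1.89 to 34.9 ± 2.69 CPM (SD, n = 2 each). Aldh3a1, an aldehyde dehydrogenase, rose from 20.6 ± 0.806 to 70.1 ± 10.7 CPM, and the glutathione transferase gene Gsta1 from 0.833 ± 0.285 to 6.14 ± 3.08 CPM. The immediate-early gene Fos fell from 227 ± 0.0219 to 1.01 ± 0.0619 CPM, Fosb from 234 ± 10.3 to 1.55 ± 0.471 CPM and Egr1 from 755 ± 4.42 to 33.5 ± 4.32 CPM.

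Of 13025 genes tested, 1098 changed (edgeR, adjusted p under 0.05), 495 upward and 603 downward, but only 159 of them by a log2 fold change of at least 1. Other named genes that rose were Mgst1 (2.11 ± 0.31), Tlcd5 (1.86 ± 0.38), Gapdhs (1.75 ± 0.41) and the nuclear non-coding RNA Neat1 (from 569 to 1725 CPM). Egr2 (-7.33 ± 0.27), Egr3 (-3.73 ± 0.13), Atf3 (-3.98 ± 0.16), the MAP kinase phosphatase Dusp1 (-3.71 ± 0.09) and the chemokine Cxcl1 (-3.99 ± 0.13) fell.

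Of 33 NRF2 and xenobiotic response genes 27 rose and none fell (camera adjusted p = 1.72e-48, but adjusted p = 0.174 with an estimated correlation), with 28 higher and 1 lower when adjusted over the list alone. Gsta4 (1.09 ± 0.04) and the cystine transporter Slc7a11 (1.05 ± 0.04) were among them. Of 24 NF-kB response genes 13 fell and none rose, 15 fell and 1 rose when adjusted over the list alone (camera adjusted p = 5.10e-43, and adjusted p = 0.101 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, fell by 2.20 on the log2 scale and Nfkbiz by 1.86. Of 34 extracellular matrix and mesenchymal genes 17 fell, with 21 lower and 1 higher when adjusted over the list alone, led by the YAP-responsive genes Ccn1 (-2.71 ± 0.03) and Ccn2 (-0.91 ± 0.05) and by Thbs1 (-0.91 ± 0.04) (camera adjusted p = 2.95e-23, and adjusted p = 0.101 with an estimated correlation). Of 25 cholesterol biosynthesis genes 12 fell by small amounts, and 17 when adjusted over the list alone, with Insig1 (-0.60 ± 0.05) and Ldlr (-0.42 ± 0.04) ahead (camera adjusted p = 4.43e-07, and adjusted p = 0.176 with an estimated correlation). Of 28 hypoxia and glycolysis genes 15 rose and 1 fell, 17 and 1 when adjusted over the list alone, among them Adm (3.76 ± 0.91), Ankrd37 (1.14 ± 0.20) and Bnip3 (0.59 ± 0.06) (camera adjusted p = 5.07e-06, and adjusted p = 0.176 with an estimated correlation). Adm is not among the largest changes named by the rule, which Gsta1 leads at 2.88. It therefore missed either the mean CPM of at least 2 or the lack of overlap between groups. Of 38 integrated stress and unfolded protein response genes 17 fell and 3 rose, 19 and 3 when adjusted over the list alone, with Ppp1r15a at -1.66 ± 0.11 (camera adjusted p = 8.88e-05, and adjusted p = 0.220 with an estimated correlation). The interferon-stimulated genes did not shift as a list: 2 of 31 rose and 1 fell, also when adjusted over the list alone, and the median log2 fold change was 0.02 (camera adjusted p = 0.754, and adjusted p = 0.825 with an estimated correlation).

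In untreated KP WT libraries, which come from a separately normalized table, Fos was at 2.77 CPM, Fosb at 2.28 CPM and Egr1 at 46.2 CPM on average, near the C271 values, while Nqo1 was between 8.20 and 9.29 CPM, near the DMSO values. The chemokine Cxcl1 was at 7.88 CPM in untreated WT, at 68.4 CPM with DMSO and at 4.28 CPM with C271. DESeq2's Wald test called 609 genes in place of 1098.

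**Figure D4:**
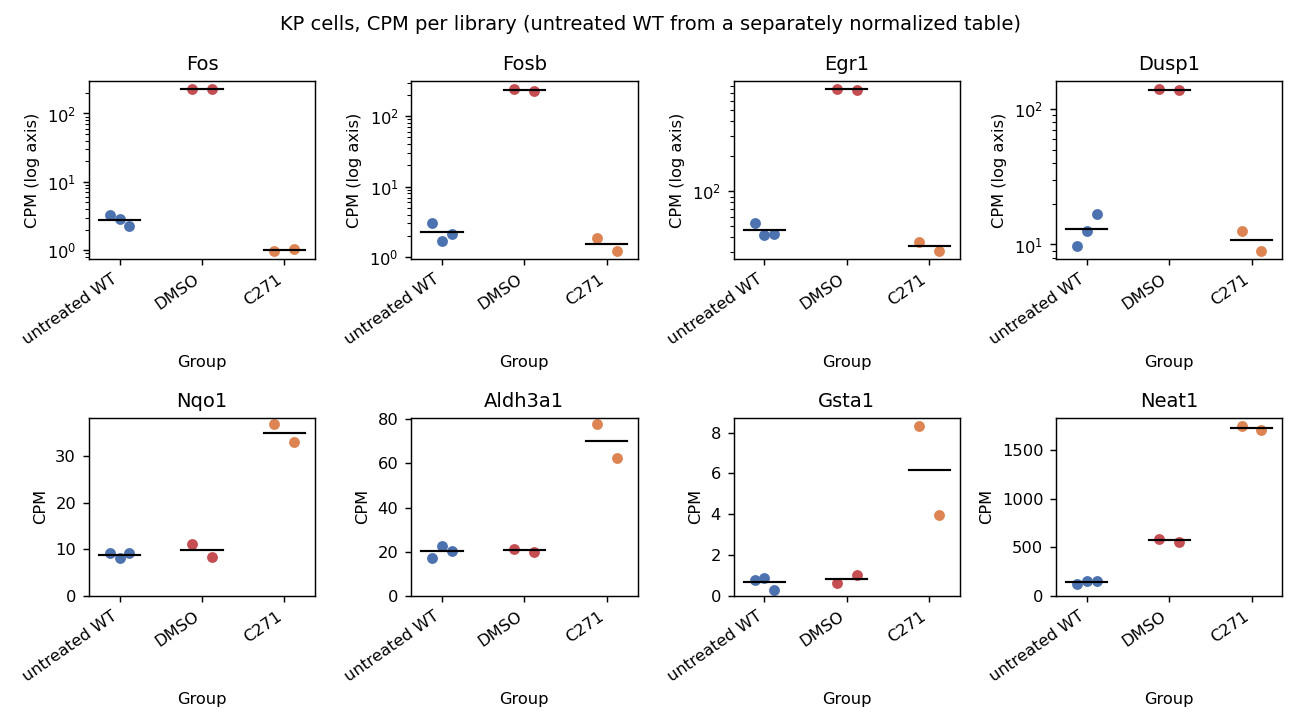
CPM in each KP library of 4 immediate-early genes (upper row, log axis) and 4 genes that rose with C271 (lower row, linear axis from 0), with points for libraries and a black bar for the group mean. Untreated WT libraries are from a separately normalized table. Fos was at 227 CPM on average with DMSO and at 2.77 CPM in untreated WT.

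In B16 cells 1 of 37 measured p53 target genes rose with loss of Tdg alone, and 2 of 37 fell with loss of Trp53 alone. Ccng1, a cyclin G gene induced by p53, rose from 125 CPM in WT to 367 CPM in Tdg KO (means, n = 2 each; log2 fold change 1.56 ± 0.14) and fell to 43.1 CPM in Trp53 KO (-1.53 ± 0.15). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 91.7 and 90.3 CPM in WT, at 338 and 401 CPM in Tdg KO and at 27.1 and 12.7 CPM in Trp53 KO.

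Ccng1 was the only gene of 13186 that changed in Tdg KO (edgeR adjusted p = 0.0135), with 660 at an unadjusted p under 0.05, and edgeR called 0 without any single Tdg KO or WT library (232 to 808 at an unadjusted p under 0.05). DESeq2's Wald test called 41 genes. Of 37 p53 target genes 22 rose when adjusted over the list alone and 1 over all genes, with Trp53inp1 at 2.30 ± 0.30, Plk2 at 1.70 ± 0.25 and Phlda3 at 1.28 ± 0.22 (camera adjusted p = 5.41e-35, but adjusted p = 0.127 with an estimated correlation). None of 40 interferon-stimulated genes passed in Tdg KO, with a median log2 fold change of 0.16 (camera adjusted p = 0.297, and adjusted p = 0.780 with an estimated correlation). In Trp53 KO 5 genes changed, with 890 at an unadjusted p under 0.05. Phlda3 (-1.99 ± 0.22), Ccng1 and Inka2 (-3.98 ± 0.46) fell. The ribosomal RNA precursor Rn45s rose from 787 ± 97.1 to 6195 ± 598 CPM, and Lars2 rose from 78.5 ± 1.14 to 254 ± 2.66 CPM. Rn45s is not polyadenylated and marks ribosomal RNA carried into a library, and the other B16 groups had between 718 and 2307 CPM of it. Group means of Lars2 ran in the same order as those of Rn45s, from WT through DKO, Tdg KO and TKO to Trp53 KO. Whether the rise of Lars2 has the same source was not tested. Of the 37 p53 target genes 2 fell in Trp53 KO, and 9 when adjusted over the list alone (camera adjusted p = 6.88e-12, and adjusted p = 0.783 with an estimated correlation). The count for Trp53 KO was 0 by edgeR without Trp53 KO replicate 1 or either WT library (1118, 290 and 265 at an unadjusted p under 0.05) and 14 without Trp53 KO replicate 2, and DESeq2's Wald test called 55.

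The B16 libraries labelled DKO differed widely from Trp53 KO: 17 of 40 interferon-stimulated, 8 of 18 antigen presentation, 23 of 37 p53 target and 26 of 38 ribosomal protein genes rose, and 23 of 40 mitotic, 21 of 45 replication and 10 of 21 melanocyte genes fell. The camera calls of these lists are lost with an estimated correlation (adjusted p = 0.248 to 0.425). Ifi27, an interferon-induced gene, was at 107 and 81.4 CPM in DKO, at 23.5 and 16.2 CPM in Trp53 KO, at 18.2 and 15.2 CPM in Tdg KO and at 13.9 and 12.9 CPM in WT. Ddx58 was at 25.2 and 18.4 CPM in DKO and at 8.32 and 2.89 CPM in Trp53 KO. Mki67, the proliferation marker Ki-67, fell by 1.62 ± 0.28 on the log2 scale, to 268 and 137 CPM from 672 and 575 CPM. Cdkn1a rose by 3.76 ± 0.56, to 255 and 282 CPM, which is above both WT libraries even though these libraries are labelled as lacking Trp53.

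Of 13186 genes 4070 changed (edgeR, adjusted p under 0.05), 1919 upward and 2151 downward, 1969 of them by a log2 fold change of at least 1. Inka2 rose from 0.303 ± 0.0575 to 29.0 ± 8.92 CPM (SD, n = 2 each). The collagen gene Col8a1 and the gasdermin gene Gsdmc2 had 0 counts in Trp53 KO, so they were at least 146-fold and at least 85.2-fold higher in DKO, taking 3 counts over the group as the floor. Cyba (chromosome 8, 122424776 to 122432930), a subunit of the NADPH oxidase, and Gcnt1 (chromosome 19, 17326141 to 17372844), a glycan-branching enzyme, had 0 counts in both DKO libraries, at least 167-fold and at least 179-fold lower than Trp53 KO. The imprinted non-coding RNA Peg13 fell from 15.5 ± 2.34 to 0.361 ± 0.163 CPM.

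Of 40 interferon-stimulated genes 17 rose and 1 fell, and 20 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.59e-06, but adjusted p = 0.313 with an estimated correlation). Rtp4 (3.05 ± 0.58), Ifitm3 (3.04 ± 0.47) and Isg15 (2.28 ± 0.57) were among them. Of 18 MHC class I antigen presentation genes 8 rose, and 10 when adjusted over the list alone, including Tap2 (4.73 ± 0.91), Tapbp (1.74 ± 0.25) and B2m (1.30 ± 0.25) (camera adjusted p = 6.71e-05, and adjusted p = 0.378 with an estimated correlation). Of 37 p53 target genes 23 rose and 1 fell, 25 and 1 when adjusted over the list alone, with Btg2 at 5.98 ± 0.53 and Trp53inp1 at 3.91 ± 0.32 (camera adjusted p = 4.88e-16, and adjusted p = 0.248 with an estimated correlation). Of 38 cytosolic ribosomal protein genes 26 rose, and 31 when adjusted over the list alone, such as Rps20 (1.14 ± 0.16) and Rpl5 (1.01 ± 0.18) (camera adjusted p = 5.20e-11, and adjusted p = 0.313 with an estimated correlation). Of 36 integrated stress and unfolded protein response genes 14 rose and 1 fell, also when adjusted over the list alone, including Trib3 (4.33 ± 1.07) and Ddit4 (3.33 ± 0.44) (camera adjusted p = 0.0312, and adjusted p = 0.404 with an estimated correlation).

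Of 40 mitotic genes 23 fell and 1 rose, 25 and 1 when adjusted over the list alone, with Anln at -1.53 ± 0.28 and Ccnb1 at -1.51 ± 0.24 (camera adjusted p = 2.15e-08, and adjusted p = 0.425 with an estimated correlation). Of 45 E2F and DNA replication genes 21 fell, and 23 when adjusted over the list alone, among them Mcm4 (-1.46 ± 0.20) and Rrm1 (-1.36 ± 0.23) (camera adjusted p = 2.79e-07, and adjusted p = 0.425 with an estimated correlation). Of 25 DNA methylation and chromatin silencing genes 14 fell and 1 rose, 16 and 1 when adjusted over the list alone, including Hells (-1.34 ± 0.15), Dnmt3b (-1.13 ± 0.23) and Dnmt1 (-0.95 ± 0.14) (camera adjusted p = 2.23e-05, and adjusted p = 0.248 with an estimated correlation). Of 24 R-loop resolution genes 10 fell, and 11 when adjusted over the list alone, such as the helicase genes Blm (-1.38 ± 0.15) and Dhx9 (-1.30 ± 0.18) (camera adjusted p = 0.000740, and adjusted p = 0.248 with an estimated correlation). Of 21 melanocyte differentiation genes 10 fell, and 12 when adjusted over the list alone, with Trpm1 (-3.80 ± 0.52) and Gpnmb (-1.57 ± 0.20) (camera adjusted p = 0.000104, and adjusted p = 0.313 with an estimated correlation). The count was 2704 without Trp53 KO replicate 1, and 1858 with only the DKO and Trp53 KO libraries in the fit. Rn45s was lower in DKO (764 and 1542 CPM) than in Trp53 KO (6618 and 5772 CPM).

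**Figure D5:**
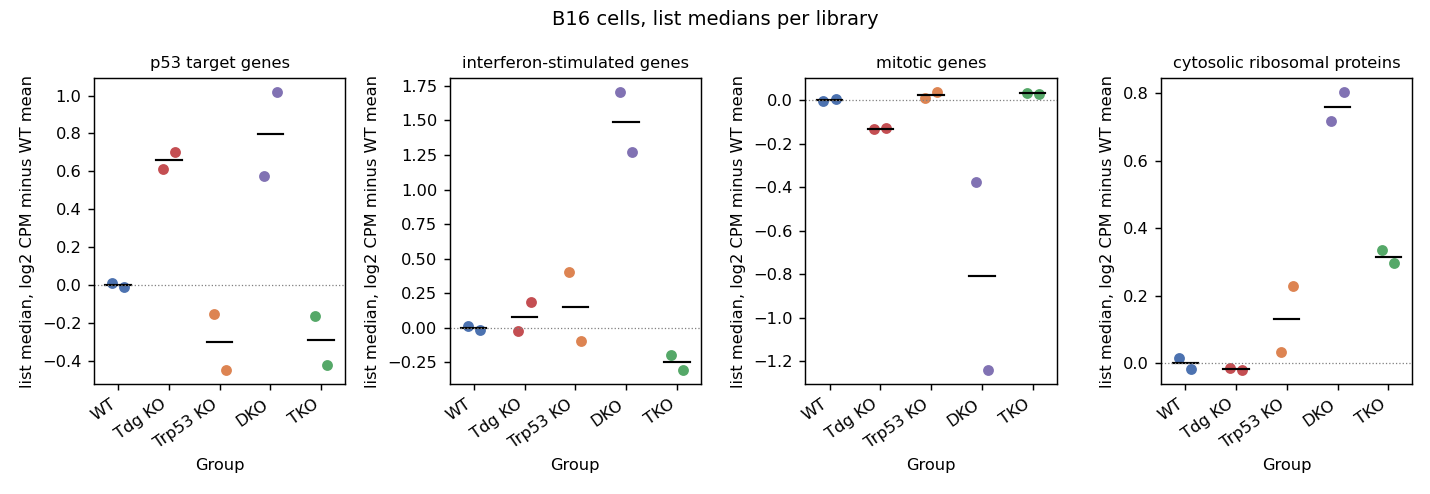
Median over each gene list of log2 CPM minus the WT mean (y axis) in each B16 library, with points for libraries and a black bar for the group mean (n = 2). The p53 target median was 0.57 and 1.02 in the libraries labelled DKO and -0.16 and -0.42 in those labelled TKO.

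The difference between the libraries labelled DKO and Trp53 KO was not that between Tdg KO and WT for 1018 genes in the interaction test (edgeR, adjusted p under 0.05). It was more positive for 328 genes and more negative for 690. The libraries labelled DKO enter this test with Cdkn1a above WT and with Cyba and Gcnt1 at 0 counts in both, so the difference cannot be assigned to Trp53 status alone. Ifi27 differed by 1.93 ± 0.37 on the log2 scale and Lgals3bp, a secreted glycoprotein induced by interferon, by 2.33 ± 0.59. They were the 2 of 40 interferon-stimulated genes that passed, with 5 when adjusted over the list alone (camera adjusted p = 2.99e-05, and adjusted p = 0.374 with an estimated correlation). Other genes with a more positive effect were Rbms3 (6.89 ± 0.61), C1s1 (5.51 ± 1.30), the extracellular superoxide dismutase Sod3 (5.30 ± 0.54) and Col4a1 (5.01 ± 1.03). Among those with a more negative effect were Peg13 (-5.43 ± 0.48), B3galt5 (-5.02 ± 0.89), Cpne4 (-4.70 ± 0.52) and S100a16 (-4.62 ± 0.67). Of 37 p53 target genes 9 had a more positive effect, and 12 when adjusted over the list alone with 1 more negative, led by Btg2 (3.62 ± 0.66) and Phlda3 (2.29 ± 0.31) (camera adjusted p = 2.99e-05, and adjusted p = 0.405 with an estimated correlation). Of 40 mitotic genes 5 had a more negative effect, and 10 when adjusted over the list alone with 1 more positive, such as Anln (-1.59 ± 0.39) (camera adjusted p = 1.75e-05, and adjusted p = 0.572 with an estimated correlation). The count was 14 and 16 without WT replicate 1 or 2, 178 and 303 without Tdg KO replicate 1 or 2, and 630 without Trp53 KO replicate 1.

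EdgeR called 0 genes between the B16 libraries labelled TKO and Trp53 KO, and DESeq2's Wald test called 102. Of the 1919 genes higher in DKO than in Trp53 KO, 1406 were lower in TKO than in DKO. Ifi27 was at 18.0 and 11.5 CPM in TKO, Ddx58 at 2.78 and 1.79 CPM, Cdkn1a at 27.0 and 6.65 CPM and Mki67 at 654 and 514 CPM. Against DKO, 4210 of 13186 genes changed (edgeR, adjusted p under 0.05), 2189 upward and 2021 downward. Of 40 interferon-stimulated genes 22 fell, and 25 when adjusted over the list alone, including Ddx58 (-3.25 ± 0.51), Samd9l (-3.22 ± 0.28) and Usp18 (-3.14 ± 0.62) (camera adjusted p = 3.29e-09, but adjusted p = 0.228 with an estimated correlation). Of 37 p53 target genes 24 fell, and 25 when adjusted over the list alone, with Ddit4l at -5.69 ± 0.58, Trp53inp1 at -5.12 ± 0.35 and Cdkn1a at -4.00 ± 0.56 (camera adjusted p = 1.87e-16, and adjusted p = 0.228 with an estimated correlation). Of 18 MHC class I antigen presentation genes 10 fell, and 11 when adjusted over the list alone, such as Tapbp (-2.13 ± 0.25) (camera adjusted p = 5.88e-05, and adjusted p = 0.445 with an estimated correlation). Of 40 mitotic genes 25 rose and 1 fell, 28 and 1 when adjusted over the list alone, with Espl1 at 1.65 ± 0.18 and Mki67 at 1.53 ± 0.27 (camera adjusted p = 9.73e-09, and adjusted p = 0.508 with an estimated correlation). Sod3 (-5.90 ± 0.41) and Inka2 (-6.60 ± 0.46) fell, and Pla2g4a had 0 counts in TKO, at least 134-fold lower than in DKO. Peg13 (5.30 ± 0.39), Armcx4 (6.03 ± 0.67), Bcan (4.84 ± 0.84) and Rab17 (4.87 ± 0.99) rose, and Cyba and Gcnt1 were at least 261-fold and at least 114-fold higher. Of the 1919 genes that rose in DKO against Trp53 KO, 1406 fell in TKO against DKO, where independent lists would share 294, and 1704 of the 2151 that fell rose, where independent lists would share 357. These comparisons share the DKO libraries. The log2 fold changes had a Pearson correlation of -0.85 across genes and a covariance of -1.06, against -0.49 and -0.09 in 20 simulations of unchanged groups, in which on average 0.1 genes were called in opposite directions. In a test chosen after the data were seen, each comparison was given a DKO library of its own, with the spread taken from the other groups. The correlation was then -0.62 or -0.66 and the covariance -0.97 or -1.01, depending on which library went to which comparison. A shift common to both DKO libraries, which may come from a single clone, stays in both of these fits. Neither these fits nor the simulations can therefore assign the reversal to the loss of Mavs.

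Between TKO and Trp53 KO edgeR called 0 genes, with 1118 at an unadjusted p under 0.05, and DESeq2's Wald test called 102. The median log2 fold change was -0.43 over 40 interferon-stimulated genes (camera adjusted p = 0.0189, and adjusted p = 0.760 with an estimated correlation), none of which passed over all genes and 1 of which fell when adjusted over the list alone. It was -0.07 over 37 p53 target genes, none of which passed (camera adjusted p = 0.927, and adjusted p = 0.973 with an estimated correlation). The count against DKO was 2173 without TKO replicate 2 and 2137 with only the TKO and DKO libraries in the fit, and the count against Trp53 KO was 5 without TKO replicate 1 and 23 without Trp53 KO replicate 2.

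The log2 fold changes measured for Tdg loss in different systems correlated weakly or not at all across genes. The r that equal effects would give at this spread was not estimated, so a low r does not show that the effects differ. For comparisons of Tdg loss in different systems Pearson's r across genes ran from -0.05 to 0.19, and genes are not independent replicates. Over all 10 pairs that share no library, those with C271 and within B16 included, it ran from -0.10 to 0.22. KP cells without Tdg and the B16 DKO against Trp53 KO gave r = 0.19 (Spearman's rho = 0.20) over 10989 genes. Here 9 genes rose in both, where 3.18 would by chance (exact hypergeometric p = 0.00213 as a description, 0.0213 after Benjamini-Hochberg adjustment over 20 overlaps). Chosen after their values were seen, these include the inflammatory caspase Casp4 (3.87 ± 0.51 in KP and 5.77 ± 1.30 in B16), the complement protease gene C1s1, ceruloplasmin (Cp), Cebpd and Tgfbr3. The KP and B16 Tdg KO against WT comparisons gave r = 0.14, and the B16 Tdg KO and DKO effects gave r = 0.22. KP Tdg KO and the tumours gave r = 0.04, with Tdg and Krt20 the 2 genes lower in both. KP Tdg KO and C271 gave r = -0.09, and 14 genes changed in opposite directions where 2.80 would by chance, among them Cxcl1, Nfkbiz and Zc3h12a, which rose without Tdg and fell with C271. For these genes the DMSO libraries lie above untreated WT: 68.4 against 7.88 CPM for Cxcl1, 31.1 against 2.81 CPM for Nfkbiz and 11.9 against 8.39 CPM for Zc3h12a, in separately normalized tables. C271 and the B16 DKO against Trp53 KO gave r = 0.03, and 113 genes fell in both where 87.8 would by chance (exact hypergeometric p = 0.00203 as a description, 0.0213 after the same adjustment).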

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

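Tests chosen only after the result was seen are those of remaining p53 activity, exchanged libraries, Tdg loss without p53 and Mavs, tumour-cell share, tumour depth, the sex of the animals and abundant genes; the tests of KP splits and of C271 handling were set before.

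Of 74 values tested in the group of 4 KPT tumours, 5 put replicate 2 far from the others. They are Xist (1944 CPM, against 1.09 to 2.83), the Y-linked genes Ddx3y (2.29 CPM, against 78.3 to 88.4) and Eif2s3y (2.76 CPM, against 78.5 to 89.0), Trp53 (35.3 CPM, against 27.1 to 28.4) and the total count (18.6 in units of 1e6). Chance marks about 1 in 20 of values picked without knowledge of them. That rate does not hold here, since Xist was named after its value was seen. Xist, Ddx3y and Eif2s3y also all follow the sex of the animal and are not separate results. In B16 cells the difference between DKO and Trp53 KO was not that between Tdg KO and WT for 1018 genes by the interaction test of edgeR, and for 14 without WT replicate 1, 16 without WT replicate 2, 178 without Tdg KO replicate 1, 303 without Tdg KO replicate 2 and 630 without Trp53 KO replicate 1. Since p53 target genes are high in the DKO libraries and both may come from one clone (correlation 0.965 over chromosomes), this difference cannot be assigned to Trp53 status alone.

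For KP cells, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many changed genes as the real split (71), which is the real split itself. The highest of the other splits gave 0, and 10 splits are too few for a share under 0.05.

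Of 37 p53 target genes 23 were higher in the B16 libraries labelled DKO than in Trp53 KO, although both are labelled as lacking Trp53. An exchange with Tdg KO libraries is argued against by Trp53 mRNA, since the lower Tdg KO library has 0.910 of the WT mean. Tdg loss raising these genes without p53 and Mavs is argued against by TKO, where the list's median change over that in DKO is -0.0577. Remaining p53 activity had the values it needs: 28 genes outside the list, lower in Trp53 KO and higher in Tdg KO than in WT, lay at a median position of 0.898 in DKO between Trp53 KO (0) and Tdg KO (1). The same genes lay at 0.314 in TKO, so part of that position may come from choosing them with the Trp53 KO libraries, and an effect of Tdg loss that needs Mavs but no p53 stays open.

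Markers of fibroblasts, endothelium, T cells and alveolar type 2 cells had higher medians in KPT tumours. The rise was not alike for all cell types: the fibroblast median was 1.16 and the macrophage and monocyte median 0.23 (permutation p = 0.03 across genes, which are not independent). This cannot decide on a lower share of tumour cells, since the mix of the other cells need not be the same in both groups. The ranges of total counts overlap by 1.46 in units of 1e6, but only through KPT replicate 2 (18.6). The KP tumours had 17.1 and 18.6, and KPT replicates 1, 3 and 4 had 16.2, 16.4 and 16.5. A difference in depth is therefore not settled by this overlap. All totals lay between 16.2 and 18.6, however, and levels were scaled to them, while the medians of the 4 lists rose by 0.603 to 1.16 on the log2 scale. The narrow range of totals argues against depth as the source of these medians. The sex of the animals as the cause is argued against, since without KPT replicate 2 all tumours have male levels of Xist and Ddx3y, and the medians of these 4 lists are then at least 0.767 of their values over all tumours. A lower share of tumour cells, as the whole cause or part of it, stays open. Trp53, knocked out in tumour cells, was at 19.9 and 21.3 CPM in KP tumours and at 27.1 to 35.3 CPM in KPT tumours (edgeR adjusted p = 0.203). The sampled region, tumour stage and an effect of Tdg loss on the tumour's surroundings were not tested.

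Immediate-early genes are lower with C271 than with DMSO. Depth or a few abundant genes are argued against, since total counts and the 10 most abundant genes can shift a level by at most 0.339 on the log2 scale between these libraries, and the smallest change among 7 such genes is -3.71; a change in total RNA per cell was not tested. The median CPM of the same genes in untreated WT cells was 0.0336 of that in the DMSO libraries (4.69 against 140, from separately normalized tables), which is what a rise in the DMSO libraries by handling needs. An effect of the solvent, of harvest or of C271 itself could each still account for it, since the untreated cells were not grown beside the treated ones as far as the labels say.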

How the results depend on the processing

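No alternative here was added after the results were seen. Apart from Tdg, Trp53 and Mavs, the genes repeated here had been picked for passing the threshold. The largest changes had also, except in the interaction, been picked for no overlap between groups. That choice left little room for reversals, so their absence among genes is no sign of stability. A change of sign counted as a reversal only where either value was past the threshold. Of 4327 repeats of named-gene results, 3572 kept their direction and side of the threshold, 747 were no longer past it, 8 came past it and 0 reversed. For gene lists 2763 of 3019 kept both, 188 fell short, 67 came past it and 1 reversed: the interferon-stimulated genes in tumours without KP tumour replicate 1 (median -0.198, camera adjusted p = 0.0467; the medians ran from -0.198 to 0.517 over single omissions). With an estimated correlation 0 of 266 list tests passed against 82 at the preset (60 with fry), so every camera call rests on the preset. Fry called 19 lists in DKO against Trp53 KO, 18 in TKO against DKO, 10 in the interaction, 10 with C271 and 3 in KP cells. It called 0 in tumours, B16 Tdg KO, Trp53 KO and TKO against Trp53 KO. Fry asks whether the members of a list change, while camera asks whether they change more than other genes. In DKO against Trp53 KO and TKO against DKO, 30.9% and 31.9% of all genes changed, so a fry call there does not back a camera call.

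Changed genes in KP cells numbered 121 without the filter, 602 by DESeq2's Wald test and 0 to 290 over single omissions. In tumours they were 265 without the filter, 283 with the replicate block, 936 by DESeq2 and 13 to 202 over omissions. C271 gave 609 by DESeq2 and 159 with a log2 fold change of at least 1. B16 Tdg KO gave 48 without the filter, 41 by DESeq2, 16 with only the compared groups, and by edgeR 0 with the block and in each omission (618 at an unadjusted p under 0.05 with the block). Trp53 KO gave 48 without the filter, 55 by DESeq2, 0 with only the compared groups (edgeR, 1700 at an unadjusted p under 0.05) and 0 to 14 over omissions. DKO against Trp53 KO gave 1858 with only the compared groups, 1969 with a log2 fold change of at least 1 and 2704 to 3392 over omissions. The interaction gave 1582 without the filter, 672 with the block, 1826 by DESeq2 and 14 to 1129 over omissions. TKO against DKO gave 2137 with only the compared groups, 2034 with a log2 fold change of at least 1 and 2173 to 3759 over omissions. TKO against Trp53 KO gave 125 without the filter, 102 by DESeq2 and 0 to 23 over omissions. Pearson's r of KP Tdg KO and DKO against Trp53 KO was 0.0758 without the filter, 0.0864 with DESeq2 and 0.125 to 0.226 over omissions. The cause of these differences was not tested.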

Other observations

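The test of a shared clone and the comparisons of DKO with WT and Tdg KO and of TKO with WT were chosen only after the results were seen; the test of chromosome copy number was set before.

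Of 19 measured extracellular matrix genes 7 rose in the B16 libraries labelled DKO against Trp53 KO, and 8 rose and 1 fell when adjusted over the list alone, with Postn at 4.11 ± 0.48, Col1a1 at 3.32 ± 0.81 and Col5a1 at 2.48 ± 0.30 (camera adjusted p = 0.0251, and adjusted p = 0.340 with an estimated correlation). The tissue inhibitor of metalloproteinases Timp1 rose by 3.07 ± 0.62 there and changed by -3.85 ± 0.65 in TKO against DKO.

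Against WT, 4834 genes changed in DKO and 4 in TKO (edgeR, adjusted p under 0.05). Of 40 interferon-stimulated genes 22 rose and 2 fell in DKO against WT, and 0 of 40 changed in TKO against WT (edgeR, where 650 of all genes had an unadjusted p under 0.05). In TKO against WT that list's median log2 fold change was -0.25 (camera adjusted p = 0.0235, and adjusted p = 0.843 with an estimated correlation). The p53 target median there was -0.30, with 2 of 37 lower (camera adjusted p = 1.43e-14, and adjusted p = 0.387 with an estimated correlation). DKO differed from Tdg KO in 4325 genes. Of 37 p53 target genes 7 rose and 3 fell between them, with a median of 0.15 over members that go both ways (camera adjusted p = 0.331, and adjusted p = 0.736 with an estimated correlation). Of 40 interferon-stimulated genes 17 rose and 1 fell between them (camera adjusted p = 3.54e-05, and adjusted p = 0.467 with an estimated correlation).

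A hypothesis formed on these data is that both DKO libraries come from one clone, so that differences of that clone add to the effect of the genotype. Medians per chromosome against WT correlated at 0.965 between the DKO libraries, and at most at 0.344 between other libraries of one edited B16 group. Cyba and Gcnt1 had 0 counts in both DKO libraries and at least 5 CPM in every other B16 library, and no other group had such a gene. Chromosome explained 0.0555 of the variance of the log2 fold changes of changed genes, so copy number of whole chromosomes is not the main source of that variance. The median of chromosome 16 against WT was -0.352 and -0.442 in the DKO libraries. Of the 4070 changed genes, 1969 changed by at least 1 on the log2 scale and weigh most in the variance. The test cannot say how many of the smaller changes come from copy number. What may belong to a clone and what to the loss of Tdg cannot be separated with 1 pair of DKO libraries. The same holds for the loss of Mavs in TKO against DKO.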
